A study of Mus musculus with 6 samples.

How the data were processed

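Poly(A) RNA of heart muscle cells from 6 mouse samples, 3 wild type and 3 TFEB-/-, was measured by RNA sequencing. Per the labels, 400 ng of total RNA extracted with TRIzol went into TruSeq Stranded mRNA libraries, which were read on an Illumina NextSeq as pairs of 75 bases. Sex, litter and processing batch are not given, nor whether each library came from a separate animal. The labels speak of 409000000 read pairs in total, 14000000 to 75000000 per sample with a median of 21000000, which is more than 6 libraries of these sizes can hold, so the depth of each library here is unknown.

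The deposited table holds 1 value per gene and library in a score taken to be CPM, counts scaled by the authors to a common library total and rounded to whole numbers. The name of the table gives kallisto, a program that assigns reads to transcripts, and CPM as its unit. Each library summed to between 999505 and 999655, and every value was a whole number, so the values are not read counts. The submitters' processing notes name STAR, HISAT2, kallisto, Salmon, RSEM, StringTie, DESeq2 and edgeR and the mouse genome build GRCm38, with no version and no statement of which tool made which value. Further scaling between libraries, or by transcript length, is not stated. Rounding limits the precision of a value to 0.5 CPM on either side, which is a large part of the value for genes of a few CPM, and no counting interval can be given.

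The table had 46517 entries. Names that a spreadsheet had turned into dates (26) were restored through their Ensembl IDs, 303 missing names were replaced by the IDs, and 46005 IDs were found in GENCODE release M21, from which positions, biotypes and transcript sequences were taken. Values that shared a symbol (67 entries beyond the first) were summed, which left 46450 symbols, 33219 of them listed at 0 in all libraries. The 12437 genes with at least 1 CPM in at least 3 libraries were tested.

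The groups were compared with limma 3.58.1 under R 4.3.3, with statmod 1.5.0, on log2(CPM + 0.5), using lmFit with genotype as the only term and eBayes with a mean-variance trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The residual degrees of freedom were 4, and with those borrowed from the trend 4.88. Count-based models were not used, since whole reads could not be recovered from rounded values. The added 0.5 CPM makes the fitted fold change of a low gene smaller than the ratio of its values. For a gene at 0 in a whole group only the values of the libraries are given. Single quantities were compared by exact two-sided permutation of the group labels, for which 0.1 is the smallest possible p with 3 against 3.

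Before the data were examined, 47 gene lists (35 pathways and 12 sets of cell type markers), the tests, most alternatives and the rule for named genes were fixed. The rule takes Tfeb, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change past the threshold with a mean of at least 2 CPM, a gene symbol and no overlap between groups, and the 5 higher and 5 lower genes with the smallest adjusted p at a mean of at least 50 CPM. For each list it takes up to 2 higher and 2 lower members past the threshold, or the 2 most abundant members where none passed, which gave 103 genes in all, of which 100 are reported and counted as named genes. Mitf, Tfe3, Galns, Scd2, Tgfb2, Slc16a3, Pgd, Pycard and Gm28437 are named beyond the rule, to complete a count or a sum, and were chosen after their values were seen. Lists with at least 3 tested members (44) were compared with the other genes by camera of limma with a preset correlation between genes of 0.01 and adjusted over the 44 lists. Camera with an estimated correlation and fry stand beside it. Fry tests a list for change from 0 on the deposited scale, not relative to the other genes. The position of a list is given relative to the median log2 fold change of all tested genes.

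The fit was tested on simulated data built from the spread within groups, with 200 changed genes at a mean of at least 5 CPM in each of 5 simulations. At the filter of 1 CPM it recovered 3.58% of 1.5-fold, 32.8% of 2-fold and 96.7% of 4-fold changes with 1.4 false calls on average, and at a filter of 5 CPM 26.6%, 90.2% and 98.8% with 2.2 false calls. The simulated libraries held no shift in scale and independent errors, so the false calls in the real data may be more. Simulated genes of the same mean were given the same spread. Differences in spread between such genes were thus absent, and recovery in the real data may differ. In splits of the real libraries that mixed the genotypes, the same fit called 14 to 58 genes. Recovery below 5 CPM was not simulated. Camera called a raised list in 5 of 5 simulations and a random list in 0 of 5. Errors were drawn independently for each gene, so these simulations cannot show how camera behaves when the genes of a list vary together. In the 7 lists later called, the estimated correlation ran from −0.146 to 0.737.

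Alternatives fixed in advance were pseudocounts of 0.1 and 2, no filter, a filter of 5 CPM, scaling by the median ratio to the geometric mean over libraries, quantile normalization, the replicate number as a block, robust hyperparameters, array quality weights, each library left out in turn, and an added limit of 1 on the absolute log2 fold change. Alternatives added after the data were seen were uniform noise of up to 0.5 CPM on either side (21 draws, median taken), also with median-ratio scaling for the share of higher genes, median-ratio scaling with a filter of 5 CPM, median-ratio scaling with a lowess correction (span 0.3) of each library on transcript GC content, and CPM recomputed without mitochondrial transcripts and their nuclear copies. Nuclear copies were genes elsewhere in the genome with a mean of at least 50 CPM whose transcript matched a mitochondrial one over at least 80% of its length at 95% identity or more.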

Results

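Messenger RNA was profiled in cardiomyocytes, the contractile cells of the heart muscle, taken from C57BL/6 mice aged 3 months. The 6 libraries formed 2 groups, 3 wild type and 3 TFEB-/-, and each library was a separate sample, though it is not stated that each came from a different animal. TFEB is a transcription factor best known for switching on genes of lysosomes and autophagy. The deposited values were whole numbers with nearly the same sum in every library. They were taken, from the name of the table, to be counts scaled to a common library total (CPM) and rounded, without scaling by transcript length, which is not stated, so the number of reads behind each value is unknown and counting error cannot be given. Library sums ran from 999505 to 999655 CPM, and 12070 to 12664 genes reached at least 1 CPM in a library. The comparison of TFEB-/- with wild type asks how cardiomyocyte transcripts differ with the genotype, with lipid metabolism and cell death as the pathways the study names. Errors after ± are SD over n = 3 libraries, and adjusted p-values are from limma unless another test is named.

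Tfeb itself was lower in all 3 TFEB-/- libraries than in every wild-type library. The gene (ENSMUSG00000023990; GRCm38 chromosome 17, 47737030 to 47792419, plus strand, protein coding) was at 17, 30 and 23 CPM in wild type and at 6, 5 and 7 CPM in TFEB-/-. The means were 23.3 ± 6.51 and 6 ± 1 CPM, a log2 fold change of −1.85 (SE 0.24, adjusted p = 0.0267). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the relatives of TFEB, Mitf was at 24.3 ± 3.51 and 19.7 ± 0.577 CPM and Tfe3 at 10.3 ± 1.53 and 13.3 ± 4.16 CPM, neither past the threshold. Tfeb transcript was thus still read in TFEB-/-, and a value per gene cannot show whether the deleted part is absent. The log2 fold change of Tfeb stayed between −2.05 and −1.65 when any one library was left out. Its adjusted p was then 0.0256 without wild type 1 and 0.0589 to 0.109 without any of the other libraries, and it was 0.112 with the replicate number as a block, within a range of 0.000505 to 0.112 over 19 alternatives.

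**Figure D1:**
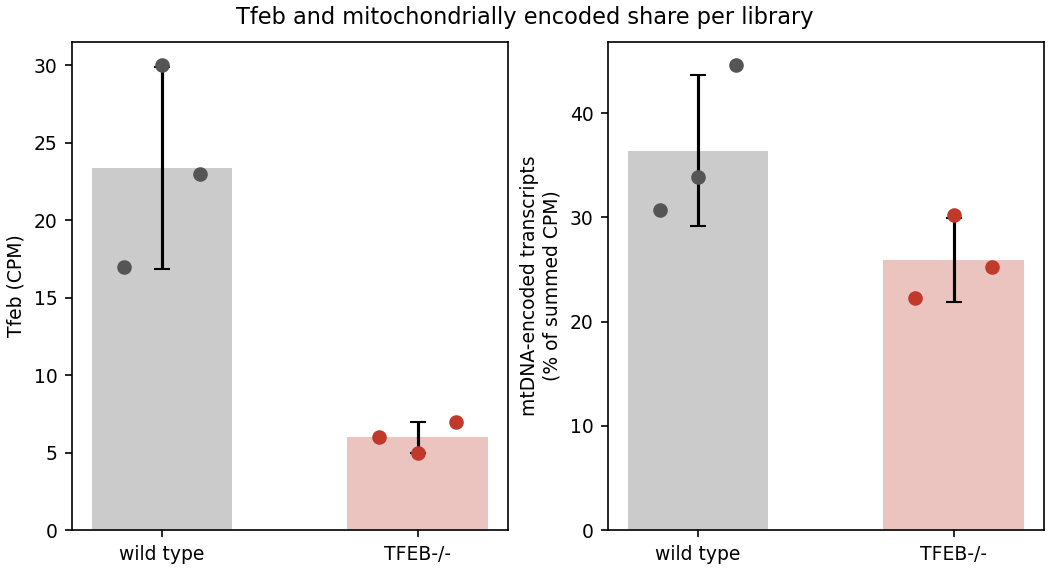
Tfeb in CPM (left) and transcripts encoded by mitochondrial DNA as a percent of all CPM (right), with bars for the group mean, error bars for the SD and points for the 3 libraries of each group. The TFEB-/- libraries lie at 5 to 7 CPM for Tfeb against 17 to 30 CPM in wild type, and at 22.2 to 30.3% against 30.7 to 44.6% for the mitochondrial share.

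In TFEB-/- cardiomyocytes the secreted factor Ndnf, the mitochondrial carrier Ucp2, skeletal muscle actin Acta1 and the stress-responsive muscle protein Ankrd1 were higher. The ketone body enzyme Bdh1, the tyrosine-degrading enzyme Fah and the acyl-CoA thioesterase Acot1 were lower. Of 12437 genes tested, 487 were higher and 65 lower at an adjusted p below 0.05. The median log2 fold change of all tested genes was 0.24 rather than 0, and transcripts of the mitochondrial genome made up 36.4 ± 7.28% of the wild-type libraries and 25.9 ± 4.06% of the TFEB-/- libraries (difference −10.5 percentage points, exact permutation p = 0.1). With each library rescaled by its median ratio, the median shift became 0.01, and 481 genes were higher and 200 lower. The groups did not overlap in 2915 genes, 23.4% of those tested, and in 3250, 26.1%, with median-ratio scaling. Chance gives 10% for independent genes, and the highest of the other 9 splits of the libraries gave 10.5% and 13.5%. Of the 552 genes past the threshold, 164 had no spread within either group, 83 of these at 0 against 1 CPM, and without these the counts were 347 higher and 41 lower. The count of higher genes was 270 without wild type 2, 248 without wild type 3, 272 without TFEB-/- 3 and 159 with the replicate number as a block. It was 780 with robust hyperparameters, 813 with rounding noise and 2241 with array weights.

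Ndnf (ENSMUSG00000049001; chromosome 6, 65671590 to 65712326, plus strand) had the largest positive log2 fold change among the genes chosen by size. It was at 3 ± 1 CPM in wild type and 54.3 ± 4.51 CPM in TFEB-/- (log2 fold change 4.01, SE 0.23, adjusted p = 0.00138). Ucp2 (ENSMUSG00000033685; chromosome 7, 100493337 to 100502020, plus strand) was at 31.3 ± 15.4 and 342.7 ± 61.5 CPM (log2 fold change 3.52, SE 0.37, adjusted p = 0.0136), a call lost without wild type 1, wild type 3, TFEB-/- 1 or TFEB-/- 3 (adjusted p = 0.051 to 0.061) and with the block (adjusted p = 0.0726). Ucp2 passed in 14 of 19 alternatives, among them median-ratio scaling (adjusted p = 0.00415). The phosphatase Dusp26, the synaptophysin-like protein Sypl2 and the aldo-keto reductase Akr1b8 were at 0.333 to 1 CPM on average in wild type and at 7.67 ± 1.15, 11.7 ± 5.51 and 10.7 ± 2.52 CPM in TFEB-/-. A further 4 of the 10 genes were listed at 0 in all wild-type libraries. These were the growth factor Tgfa, at 8, 5 and 4 CPM in TFEB-/-, the lysophosphatidic acid receptor Lpar3, at 8, 3 and 5 CPM, cytidine deaminase Cda, at 6, 3 and 3 CPM, and Rasgef1a, at 7, 2 and 3 CPM. Ndnf passed the threshold in every alternative but the replicate block and Akr1b8 in all 19. Tgfa and Cda passed in 16 of 17, lost with the block, and were not tested in the 2 with a filter of 5 CPM. The calls of Dusp26, Lpar3, Rasgef1a and Sypl2 were lost with the block and without wild type 2, wild type 3 or TFEB-/- 3 (adjusted p = 0.0564 to 0.12).

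Among genes that were lower, Fah (ENSMUSG00000030630; chromosome 7, 84585159 to 84606722, minus strand) was at 22.7 ± 8.14 CPM in wild type and 2.67 ± 0.577 CPM in TFEB-/- (log2 fold change −2.83, SE 0.29, adjusted p = 0.013), a call lost without TFEB-/- 3 (adjusted p = 0.058) and with the block (adjusted p = 0.0681). The guanylate-binding protein Gbp6 (12.3 ± 2.52 and 2 ± 1 CPM), the glycolytic regulator Pfkfb1 (11.3 ± 4.51 and 1.67 ± 0.577 CPM), the amylase Amy1 (6 ± 1.73 and 1 ± 0 CPM), Rhbdl3 (8.33 ± 2.31 and 1.67 ± 0.577 CPM) and Art4 (13.7 ± 4.16 and 3 ± 1 CPM) fell with log2 fold changes from −2.43 to −2.01. Each of these 5 calls was lost without wild type 2, wild type 3 or TFEB-/- 3 (adjusted p = 0.0577 to 0.147). They passed in 14 of 19, 14 of 19, 12 of 17, 12 of 19 and 11 of 19 alternatives. The phosphodiesterase Pde7a was at 18.3 ± 1.53 and 4.67 ± 0.577 CPM (log2 fold change −1.87, SE 0.12, adjusted p = 0.00172), and it passed the threshold in every alternative.

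**Figure D2:**
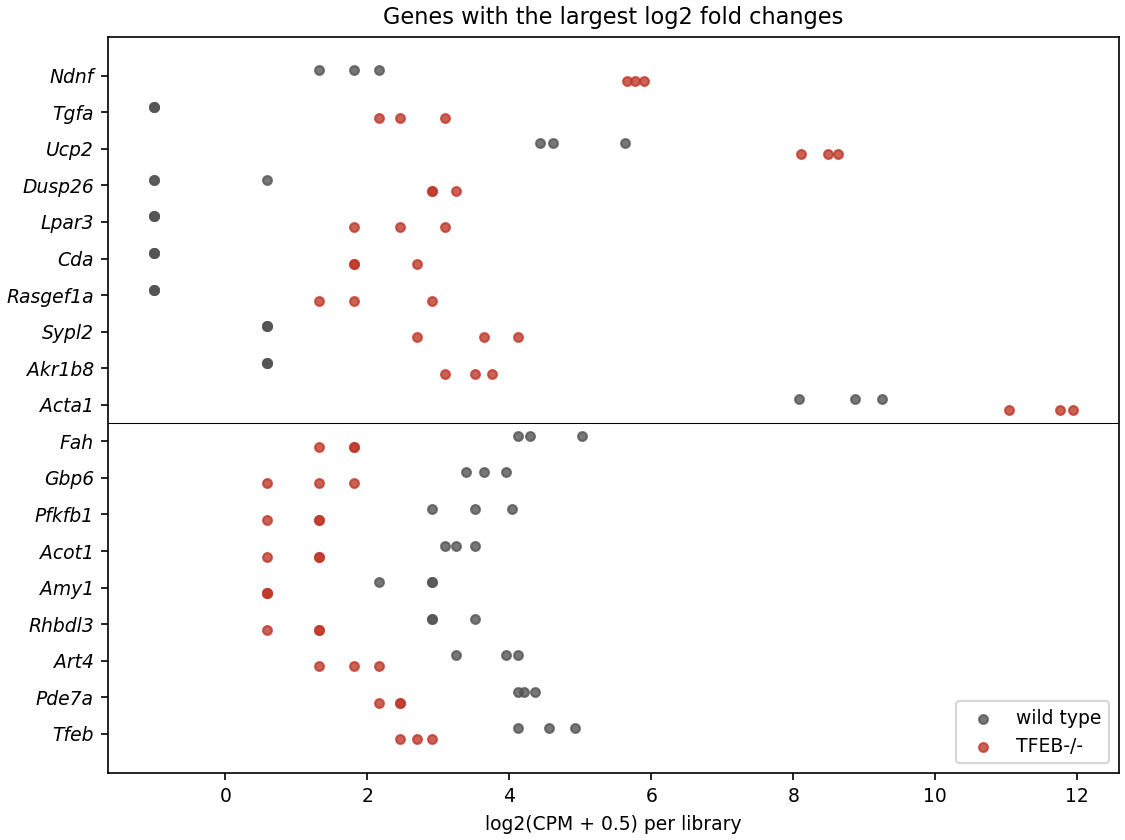
Log2(CPM + 0.5) in each library, wild type in grey and TFEB-/- in red, for genes with the largest positive (top, 10 genes) and the largest negative (bottom, 9 genes) log2 fold changes chosen by the rule. Lack of overlap between the groups was a condition of the choice, and many values lie near the floor of the scale.

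Abundant transcripts changed as well. Among genes with a mean of at least 50 CPM, the smallest adjusted p-values for higher genes belonged to Ankrd1, Cox19, Slc12a4, Tnip1 and Ucp2. Cox19, an assembly factor of cytochrome c oxidase, was at 35.3 ± 4.04 CPM in wild type and 78.0 ± 3 CPM in TFEB-/- (log2 fold change 1.14, SE 0.10, adjusted p = 0.00668). Tnip1, an inhibitor of NF-kB signalling, was at 39.3 ± 6.66 and 99.3 ± 7.64 CPM (log2 fold change 1.34), and the potassium-chloride cotransporter Slc12a4 was at 48.3 ± 3.79 and 85.0 ± 4.36 CPM (log2 fold change 0.81, adjusted p = 0.0114), a call lost with median-ratio scaling (log2 fold change 0.57, adjusted p = 0.076) that passed in 12 of 19 alternatives. The lower genes were Bdh1, Eif4e, Ugp2, Ipo13 and Fam134b. Ugp2, which makes UDP-glucose for glycogen, was at 224.3 ± 12.1 and 102.3 ± 19.6 CPM (log2 fold change −1.14, SE 0.15, adjusted p = 0.0267). The cap-binding translation factor Eif4e (94.7 ± 4.04 and 69.3 ± 2.52 CPM), the import receptor Ipo13 (74.3 ± 9.50 and 41.7 ± 4.16 CPM) and the ER-phagy receptor Fam134b (145.7 ± 18.2 and 88.0 ± 5.29 CPM) had log2 fold changes of −0.45, −0.82 and −0.72. The Eif4e call passed in 11 of 19 alternatives and was lost with rounding noise, a filter of 5 CPM, the block, robust hyperparameters and without wild type 2 or any 1 TFEB-/- library (adjusted p = 0.0626 to 0.114). The calls of Tnip1, Ugp2, Ipo13 and Fam134b were lost with the block and without wild type 3, TFEB-/- 1 or TFEB-/- 3 (adjusted p = 0.0548 to 0.137).

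Lysosomal and autophagy genes, the best-known targets of TFEB, were not called lower as a group. Of 44 lysosomal enzymes and membrane proteins, 3 were higher and 0 lower, and 9 were higher and 1 lower when adjusted over the list alone. The list median lay 0.03 above the median of all genes (camera adjusted p = 0.192). An unadjusted p below 0.05 in limma was found for 20 of the 44, against 2904 of the 12437 genes tested. The mixed fry test, which counts changes in either direction, called the list (adjusted p = 0.000178), as it did 27 of the 44 lists tested. The cathepsin Ctsz rose from 7.33 ± 0.577 to 16.3 ± 1.15 CPM (log2 fold change 1.10, SE 0.09, adjusted p = 0.0046), the sulfatase Galns rose from 4 ± 0 to 9 ± 1 CPM (log2 fold change 1.07), and the galactosidase Gla was at 2 CPM in each wild-type and 3 CPM in each TFEB-/- library, a difference of 1 rounding step that was no longer called with median-ratio scaling or rounding noise and passed in 10 of 17 alternatives. With median-ratio scaling the list had 2 higher and 1 lower member. None of the 18 vacuolar ATPase subunits, 43 autophagy genes or 26 genes of lysosomal nutrient sensing passed the threshold in limma, and 6, 11 and 4 of them had an unadjusted p below 0.05. Their camera adjusted p-values were 0.447, 0.490 and 0.768. The autophagy receptor Sqstm1 was at 347.7 ± 32.3 and 576.0 ± 93.0 CPM (log2 fold change 0.72, adjusted p = 0.0697). The other abundant members, Pink1, Atp6v0c, Atp6ap1, Tsc2 and Lamtor1, had log2 fold changes of 0.14 to 0.31, or −0.09 to 0.07 relative to the median of all genes. The MiT-TFE family list, 3 measured members including Tfeb, was called lower (camera adjusted p = 0.029). Tfeb, the targeted gene, was its only member past the threshold, so the call is not evidence on the relatives of TFEB. The call was lost with an estimated correlation (adjusted p = 0.794), without wild type 3 (adjusted p = 0.0952) and without TFEB-/- 2 (adjusted p = 0.0958). It was also lost with median-ratio scaling, alike with a filter of 5 CPM added, quantile normalization, the block, array weights and CPM without mitochondrial transcripts (adjusted p = 0.0565 to 0.215). It passed in 10 of 19 camera alternatives.

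Genes of fatty acid uptake and oxidation lay low relative to all genes, while their own median log2 fold change was −0.035. Of the 35 measured members, 3 lay above the median of all genes, and the list median was −0.27 relative to it. The preset-correlation camera test called the list lower (adjusted p = 7.5e-07), and with an estimated correlation the call was lost (adjusted p = 0.961). It passed in 18 of 19 camera alternatives. Fry, which tests for change from 0 rather than relative to all genes, did not call it (adjusted p = 0.505). In the same libraries the endothelial markers had a median of −0.39 relative to all genes and the mitochondrial share was lower by −10.5 percentage points. The endothelial median was −0.084 with array weights, and a link between these shifts was not tested. A single member passed the gene-level threshold, Acot1, a cytosolic thioesterase that releases free fatty acids from acyl-CoA, which fell from 9.33 ± 1.53 to 1.67 ± 0.577 CPM (log2 fold change −2.21, SE 0.25, adjusted p = 0.0182). The Acot1 call was lost with the block (adjusted p = 0.109) and when any 1 library but TFEB-/- 1 or TFEB-/- 2 was left out (adjusted p = 0.0549 to 0.077). With median-ratio scaling 4 members were lower, and these included lipoprotein lipase Lpl (2300.0 ± 442 and 1414 ± 54.6 CPM), malonyl-CoA decarboxylase Mlycd (106.3 ± 7.37 and 79.3 ± 5.69 CPM) and the mitochondrial thioesterase Acot2 (56.0 ± 3.61 and 36.0 ± 5.29 CPM). The fatty acid transporter Cd36 was at 774.7 ± 33.5 and 471.7 ± 113 CPM (log2 fold change −0.74, adjusted p = 0.111). Lpl, Mlycd, Acot2 and Cd36 were picked out after their values were seen.

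Genes for catabolism of branched-chain amino acids and ketone bodies also lay low relative to all genes, with a median log2 fold change of −0.0145. Of 24 measured genes 4 lay above the median of all genes, and the list median was −0.25 relative to it (camera adjusted p = 0.00149, and adjusted p = 0.961 with an estimated correlation). Fry, which tests for change from 0 rather than relative to all genes, did not call the list (adjusted p = 0.607). The endothelial median was −0.39, and a link between the lists was not tested. Bdh1 (ENSMUSG00000046598; chromosome 16, 31422280 to 31458901, plus strand), the mitochondrial dehydrogenase of the main ketone body, was its one member past the threshold, and it fell from 121.7 ± 17.5 to 54.0 ± 3 CPM (log2 fold change −1.16, SE 0.12, adjusted p = 0.0132), a call lost with the block (adjusted p = 0.0911) and without wild type 2, TFEB-/- 1 or TFEB-/- 3 (adjusted p = 0.0562 to 0.0583). With median-ratio scaling 4 members were lower, and 5 with a filter of 5 CPM added. None of the 21 regulators of the PPAR, PGC-1 and ERR family passed in limma, with 2 at an unadjusted p below 0.05 (camera adjusted p = 0.238). With median-ratio scaling 1 member was lower and the list was called lower (adjusted p = 0.0448), and with an estimated correlation on the deposited scale it was not (adjusted p = 0.961). Esrra and Perm1, the most abundant of these, had log2 fold changes of 0.18 and −0.22.

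Lipid synthesis contained several higher genes. Of 19 genes of fatty acid synthesis and desaturation 3 were higher and 0 lower, and 8 were higher when adjusted over the list alone (camera adjusted p = 0.445). The delta-5 desaturase Fads1 rose from 5.33 ± 0.577 to 16.7 ± 4.04 CPM (log2 fold change 1.54, SE 0.20, adjusted p = 0.0245), the stearoyl-CoA desaturase Scd2 from 4.33 ± 1.53 to 31.3 ± 17.1 CPM (log2 fold change 2.64), and Fads3 from 41.7 ± 0.577 to 59.0 ± 3.61 CPM (log2 fold change 0.50). In sterol synthesis and uptake 2 of 24 genes were higher, Idi1 and Nsdhl, both enzymes of the cholesterol pathway, at 3 ± 0 and 5.33 ± 0.577 CPM and at 3.67 ± 0.577 and 7 ± 0 CPM (list camera adjusted p = 0.199). The lipid droplet coat protein Plin3 rose from 131.3 ± 8.39 to 259.3 ± 37.4 CPM (log2 fold change 0.97, SE 0.13, adjusted p = 0.0267), the only one of 29 triacylglycerol and droplet genes to pass (camera adjusted p = 0.445). Of 36 sphingolipid and phospholipid genes 1 was higher, the lipid phosphatase Plpp2 at 1 ± 0 and 2.33 ± 0.577 CPM, and 5 were higher when adjusted over the list alone (camera adjusted p = 0.704). The calls of Fads3, Idi1 and Plpp2 were lost with median-ratio scaling and with rounding noise, and passed in 6 of 19, 10 of 19 and 3 of 17 alternatives. Those of Fads1 and Plin3 were lost with the block and without any 1 wild-type library or TFEB-/- 3, and that of Plin3 also without TFEB-/- 1 (adjusted p = 0.0554 to 0.109). The Nsdhl call passed in 12 of 19 alternatives and was lost with quantile normalization, the block, and without wild type 1, wild type 2 or any 1 TFEB-/- library (adjusted p = 0.0538 to 0.11).

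**Figure D3:**
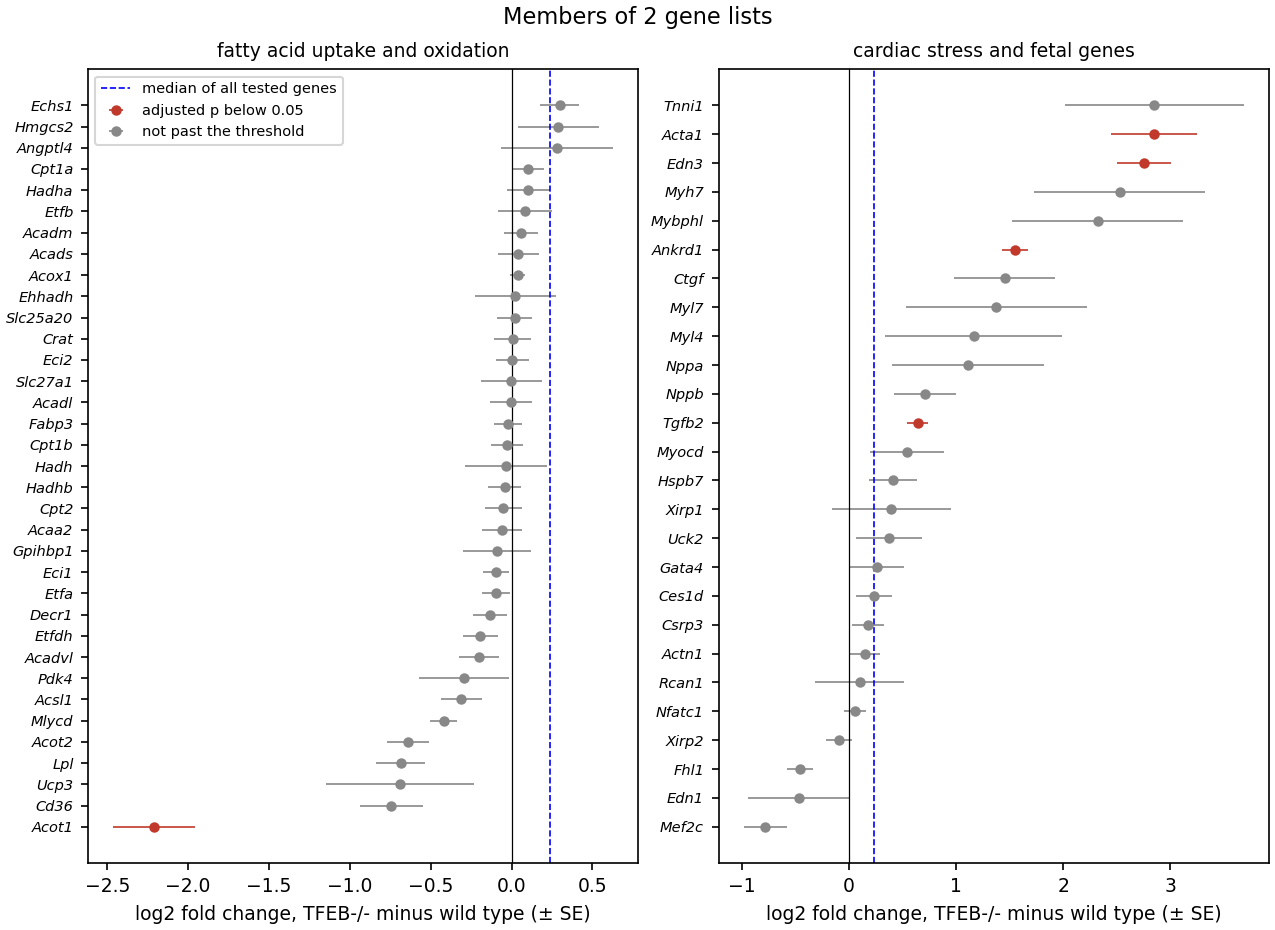
Log2 fold change of each measured member with its SE for fatty acid uptake and oxidation (left) and for cardiac stress and fetal genes (right), with members past an adjusted p of 0.05 in red and a dashed line at the median of all tested genes, 0.24. In the left panel 3 of 35 members lie above the dashed line, and in the right panel 17 of 26 do.

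Of the cell death lists none was called by camera, and a few members of low abundance were higher. The mixed fry test called all 4, intrinsic apoptosis (adjusted p = 1.5e-07), death receptors (adjusted p = 0.00564), ferroptosis (adjusted p = 0.00564) and p53 targets (adjusted p = 0.0144). That test called 27 of the 44 lists in all, so these calls are not particular to cell death. The intrinsic apoptosis list also holds Bid, which had no spread within either group. The fit recovered 32.8% of simulated 2-fold changes in genes with a mean of at least 5 CPM, where genes of the same mean shared 1 spread. Changes in genes below that mean were not simulated. A gene not past the threshold is therefore not shown to be unchanged. In intrinsic apoptosis 2 of 29 genes were higher and 0 lower (camera adjusted p = 0.782). Bok, a pore-forming member of the BCL2 family, was at 1 ± 0 CPM in wild type and 3.33 ± 0.577 CPM in TFEB-/- (log2 fold change 1.34, SE 0.11, adjusted p = 0.00602), a call lost with the block (adjusted p = 0.0666). Bid, which links death receptors to mitochondria, was listed at 0 in each wild-type library and at 1 CPM in each TFEB-/- library, and its call was lost with rounding noise and robust hyperparameters. Among 21 genes of death receptors, necroptosis and pyroptosis the TNF receptor Tnfrsf1a rose from 14.3 ± 1.53 to 23.0 ± 1 CPM (log2 fold change 0.67, SE 0.09, adjusted p = 0.0317). It passed in 11 of 19 alternatives, and was lost with the block, with GC correction, with CPM without mitochondrial transcripts and when any 1 library but wild type 1 was left out (adjusted p = 0.0585 to 0.118). Together with Pycard, 2 members were higher when adjusted over the list alone (camera adjusted p = 0.490). The p53 target Phlda3 rose from 2.33 ± 0.577 to 5.33 ± 0.577 CPM, 1 of 24 in its list (camera adjusted p = 0.678), a call lost with the block and when any 1 library but wild type 2 was left out (adjusted p = 0.0807 to 0.136). None of the 19 genes of ferroptosis and iron passed in limma, and 7 had an unadjusted p below 0.05 (camera adjusted p = 0.238). Gpx4, which removes lipid peroxides, was at 492.0 ± 65.4 and 693.0 ± 56.3 CPM (log2 fold change 0.50, adjusted p = 0.102), and the ferritin chain Fth1 had a log2 fold change of 0.34.

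Cardiac stress and fetal genes included some of the most strongly changed abundant transcripts. Of 26 measured members 4 were higher and 0 lower. Ankrd1 (ENSMUSG00000024803; chromosome 19, 36111961 to 36120099, minus strand) rose from 1209 ± 150 to 3528 ± 312 CPM (log2 fold change 1.55, SE 0.12, adjusted p = 0.0046) and passed the threshold in every alternative. Acta1 (ENSMUSG00000031972; chromosome 8, 123891769 to 123894751, minus strand), the actin of skeletal muscle and of the fetal heart, rose from 448.3 ± 170 to 3162 ± 948 CPM (log2 fold change 2.85, SE 0.40, adjusted p = 0.0322). The Acta1 call was lost with quantile normalization (adjusted p = 0.055) and without any one of the 6 libraries (adjusted p = 0.0532 to 0.119, log2 fold change 2.52 to 3.12). The endothelin Edn3 was at 1 CPM in each wild-type library and at 14, 7 and 9 CPM in TFEB-/-, a call lost with the block (adjusted p = 0.0751) and without wild type 3 (adjusted p = 0.0535). Tgfb2 rose from 4.33 ± 0.577 to 7 ± 0 CPM, a call lost with median-ratio scaling. Tested against the other genes the list did not pass (camera adjusted p = 0.490, median 0.24 above all genes). Of 27 sarcomere genes none passed in limma, with 8 at an unadjusted p below 0.05 (camera adjusted p = 0.433). The main myosin and actin of the adult heart, Myh6 and Actc1, had log2 fold changes of 0.31 and 0.32. Of 38 genes of calcium handling and ion channels 1 was higher and 0 lower (camera adjusted p = 0.299).

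Transcripts encoded by the mitochondrial genome lay low relative to all genes, with a median log2 fold change of −0.38, and fry did not call them (adjusted p = 0.152). All 13 measured genes lay below the median of all genes, and the list median was −0.62 relative to it (camera adjusted p = 9.2e-10). The call was lost with an estimated correlation (adjusted p = 0.794) and with quantile normalization (adjusted p = 0.0586). The endothelial median in the same libraries was −0.39, and a link between the lists was not tested. None of the 13 passed alone in limma, with 5 at an unadjusted p below 0.05, and mt-Co1 and mt-Cytb, the most abundant, had log2 fold changes of −0.40 and −0.24. Reads of mt-Co3 cannot be told from those of Gm28437, a nuclear copy identical over 783 bases. The transcripts of mt-Co2, mt-Atp6 and mt-Nd3 likewise have nuclear copies of 99.7 to 100% identity. A copy of mt-Co1 matches it over 483 bases at 99.8% identity, which is a part of that transcript. The separate values of these genes and the list carry the same limit, for mt-Co1 at least over the matched part. The sum of all mitochondrial transcripts and copies was 41.5 ± 7.41% and 31.2 ± 5.86% of CPM (exact permutation p = 0.2). In the table mt-Co3 had 36929 ± 15430 and 13851 ± 3352 CPM and the copy 6087 ± 4830 and 14047 ± 5880 CPM, so only their sum is interpretable, 43016 ± 10785 and 27898 ± 6670 CPM (exact permutation p = 0.2). The 55 nuclear-encoded respiratory chain genes had a median of −0.18 relative to all genes, with 6 above it and none past the threshold in limma (2 at an unadjusted p below 0.05, camera adjusted p = 0.0573). That list was called lower with median-ratio scaling (adjusted p = 5.9e-05) and with the block (adjusted p = 0.0214), and with an estimated correlation on the deposited scale it was not (adjusted p = 0.961). Its most abundant members, Atp5b and Atp5a1, had log2 fold changes of 0.27 and 0.06.

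In glucose metabolism 3 of 39 genes were higher and 1 lower (camera adjusted p = 0.885). The platelet-type phosphofructokinase Pfkp rose from 35.0 ± 6.08 to 96.3 ± 10.4 CPM (log2 fold change 1.46, SE 0.16, adjusted p = 0.0164). Pyruvate dehydrogenase kinase Pdk3 was at 1 CPM in each wild-type and 5 CPM in each TFEB-/- library and passed the threshold in all 19 alternatives. The lactate transporter Slc16a3 was at 1 ± 0 and 2.67 ± 0.577 CPM, a call lost with median-ratio scaling. Pfkfb1 was the lower member. Among 31 NRF2 targets and antioxidant genes 3 were higher (camera adjusted p = 0.312). Glutathione peroxidase Gpx1 rose from 25.7 ± 4.73 to 85.0 ± 18.5 CPM (log2 fold change 1.70, SE 0.21, adjusted p = 0.0238), and the pentose phosphate enzymes Tkt and Pgd rose from 13.0 ± 1 to 22.0 ± 2 CPM and from 23.0 ± 1 to 41.0 ± 7 CPM. In the integrated stress response the serine synthesis enzyme Psat1 (1 CPM in each wild-type and 3 CPM in each TFEB-/- library) and the amino acid transporter Slc7a5 (4.67 ± 0.577 and 10.7 ± 1.53 CPM) were higher, 2 of 28 genes (camera adjusted p = 0.279). The calls of Pfkp, Gpx1, Tkt and Slc7a5 were lost with the block and without TFEB-/- 1 or TFEB-/- 3 (adjusted p = 0.06 to 0.114). They passed in 15, 14, 14 and 12 of 19 alternatives. None of the 23 genes of the unfolded protein response passed in limma and 0 had an unadjusted p below 0.05 (camera adjusted p = 0.0573), with Hspa5 and Calr at log2 fold changes of −0.10 and 0.10.

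The 29 measured interferon-stimulated genes were called lower as a list (median −0.21 relative to all genes, camera adjusted p = 0.00866). In the same libraries the endothelial median was −0.39 and the mitochondrial share was lower by −10.5 percentage points, and a link to either was not tested. Ifit2 was higher at 2 ± 0 and 5.33 ± 0.577 CPM, a call lost with the block (adjusted p = 0.052). Ifi44 was at 1 CPM in each wild-type library and listed at 0 in TFEB-/-, a single rounding step whose call was lost with rounding noise (adjusted p = 0.102) and robust hyperparameters (adjusted p = 0.0794). The list's adjusted p was 0.794 with an estimated correlation, and among the 9 members left by a filter of 5 CPM the test turned to the other direction (adjusted p = 0.874, within a range of 0.000107 to 0.982 over 19 camera alternatives). The call was also lost with median-ratio scaling (adjusted p = 0.0632), quantile normalization (adjusted p = 0.0931), GC correction (adjusted p = 0.0989) and CPM without mitochondrial transcripts (adjusted p = 0.0613), without wild type 3 (adjusted p = 0.0788) and without TFEB-/- 2 (adjusted p = 0.0771). Cytosolic ribosomal protein genes were called higher (33 of 39 above the median of all genes, list median 0.12 above it, camera adjusted p = 0.0312), and the call was lost with an estimated correlation (adjusted p = 0.961). It was also lost without wild type 1 (adjusted p = 0.508), without TFEB-/- 1 (adjusted p = 0.137) and without TFEB-/- 3 (adjusted p = 0.138). The block (adjusted p = 0.154), array weights (adjusted p = 0.286) and GC correction (adjusted p = 0.0989) ended it as well. None of these 39 genes passed alone in limma, 12 had an unadjusted p below 0.05, and the abundant Rplp0 and Rpl4 had log2 fold changes of 0.24 and 0.40. Thrombospondin Thbs4 rose from 2.67 ± 0.577 to 8.33 ± 0.577 CPM, 1 of 30 genes of extracellular matrix and TGF-beta (camera adjusted p = 0.343), a call lost with the block (adjusted p = 0.101) and without TFEB-/- 1 or TFEB-/- 3 (adjusted p = 0.0599 and 0.0651).

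No member passed the threshold in limma among 31 inflammatory and NF-kB genes, 27 immediate early genes, 21 heat shock and chaperone genes, 19 circadian clock genes and 23 ubiquitin-proteasome and atrophy genes, with 1, 2, 1, 3 and 9 at an unadjusted p below 0.05. Their camera adjusted p-values were 0.782, 0.199, 0.881, 0.953 and 0.793. Abundant members, Socs3, Nfkbia, Egr1, Fos, Cryab, Hsp90ab1, Bhlhe40, Tef and Ubb, had log2 fold changes of 0.12 to 0.74. For these 5 lists, and for the autophagy, p53 and calcium handling lists, the median or the mean relative to all genes differed in sign from the direction of the camera test. The Y-linked genes Eif2s3y, at 33.0 ± 3.61 and 41.0 ± 3 CPM, and Ddx3y, at 9.67 ± 2.08 and 10 ± 1 CPM, were present in all 6 libraries, and none of 4 sex-linked genes passed in limma (1 at an unadjusted p below 0.05, camera adjusted p = 0.830).

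Markers of other heart cells were measured to describe the cell preparations. Endothelial markers were called lower (1 of 15 above the median of all genes, list median −0.39 relative to it, camera adjusted p = 0.000176), and the call was lost with an estimated correlation (adjusted p = 0.794) and with array weights (adjusted p = 0.225). None of the 15 passed alone in limma, with 2 at an unadjusted p below 0.05. Aqp1 was at 183.0 ± 32.0 and 163.0 ± 47.8 CPM and Fabp4 at 164.0 ± 15.1 and 149.7 ± 33.3 CPM. Of 14 fibroblast markers Gsn rose from 134.7 ± 5.13 to 228.0 ± 22.9 CPM and Pdgfra was at 2 CPM in each wild-type and 3 CPM in each TFEB-/- library (camera adjusted p = 0.279), and both calls were lost with median-ratio scaling, quantile normalization and the block (adjusted p = 0.0548 to 0.336). Gsn passed in 9 of 19 alternatives and was also lost without any 1 wild-type library or TFEB-/- 3 (adjusted p = 0.0553 to 0.094), and Pdgfra passed in 10 of 17. The pericyte proteoglycan Cspg4 rose from 11 ± 1 to 23.7 ± 4.62 CPM, 1 of 12 smooth muscle and pericyte markers (camera adjusted p = 0.155). The Cspg4 call passed in 12 of 19 alternatives and was lost with quantile normalization, the block, and when any 1 library but TFEB-/- 1 was left out (adjusted p = 0.0671 to 0.127). Of 13 macrophage and monocyte markers, Tyrobp was listed at 0 in wild type and at 1 CPM in each TFEB-/- library (camera adjusted p = 0.159). Among 15 ventricular cardiomyocyte markers the transcription factor Hey2 was lower, at 2 CPM in each wild-type and 1 CPM in each TFEB-/- library (camera adjusted p = 0.509). The calls of Pdgfra, Tyrobp and Hey2, each a single rounding step, were lost with rounding noise and with robust hyperparameters.

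None of the 10 atrial cardiomyocyte markers passed in limma (2 at an unadjusted p below 0.05, camera adjusted p = 0.885), and wild-type libraries differed widely in them. Nppa was at 600.7 ± 509 and 1075 ± 410 CPM and Myl4 at 150 ± 132 and 239.7 ± 21.1 CPM, and the median and mean of the list lay 0.85 and 0.57 above all genes while the camera test pointed lower. None passed among 5 erythroid and platelet, 6 Schwann and neuronal and 8 epicardial and mesothelial markers (0, 1 and 0 at an unadjusted p below 0.05, camera adjusted p = 0.155, 0.565 and 0.126). Hba-a1, Hbb-bs, Dbh, Upk3b and Msln were each below 10 CPM on average in both groups, and Prnp was at 129.7 ± 8.08 and 122.3 ± 16.4 CPM. Of the adipocyte markers 2 could be measured, Car3 and Cfd, both below 3 CPM on average, and no neutrophil or lymphocyte marker reached the filter.

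**Figure D4:**
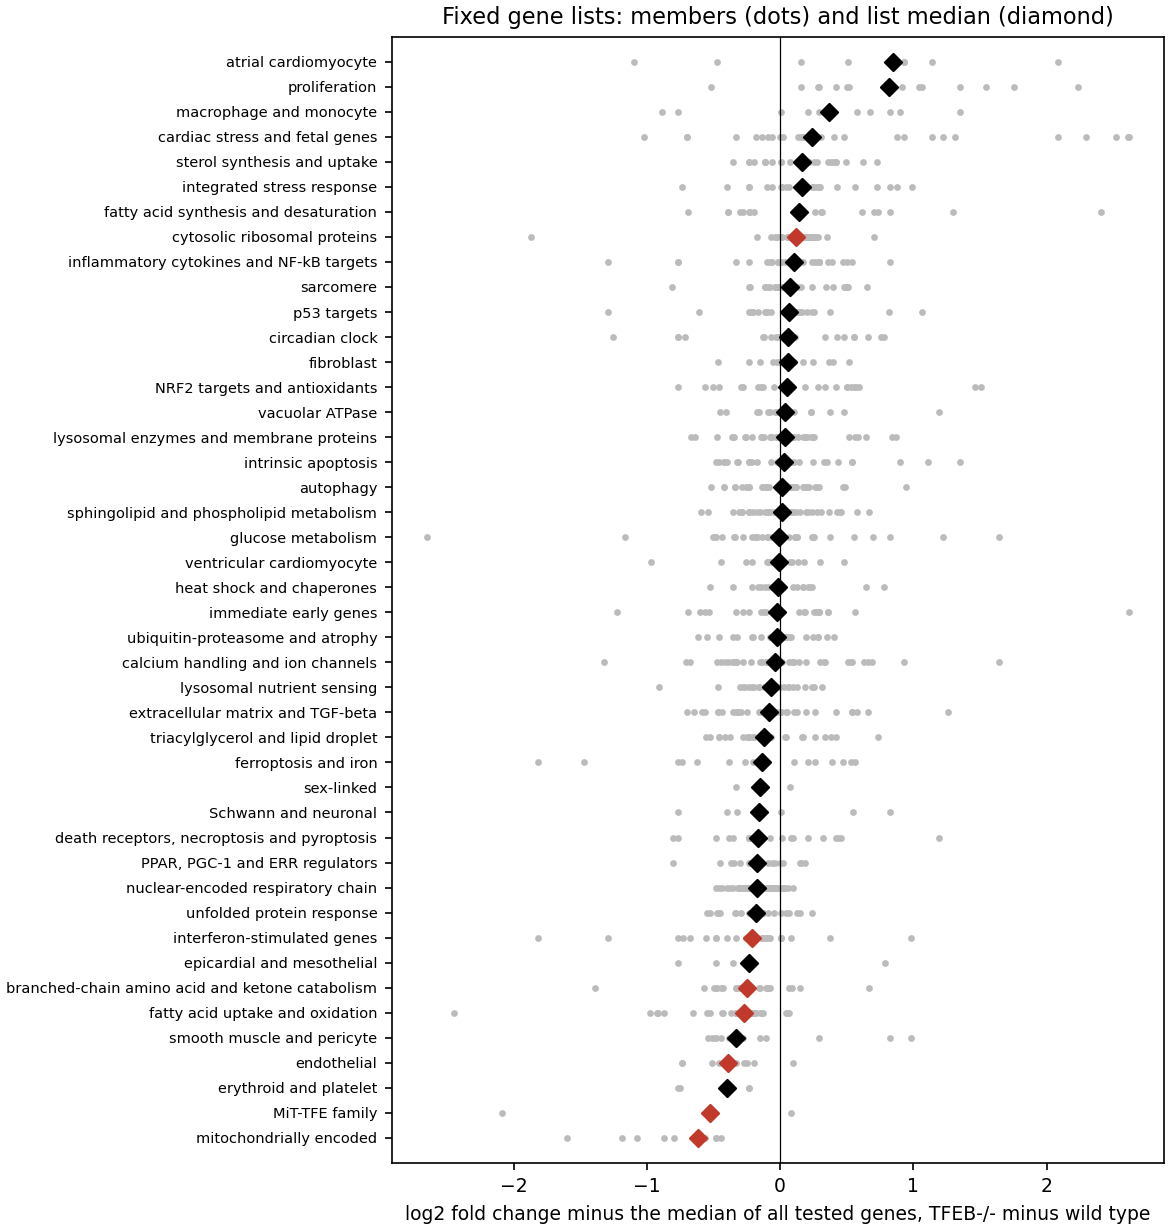
Log2 fold change of each member (dots) and of the list median (diamonds), relative to the median of all tested genes, for the 44 lists with at least 3 measured members. Red diamonds mark the 7 lists called by camera with the preset correlation, 6 of them lower and 1, the cytosolic ribosomal proteins, higher, and 0 lists were called with an estimated correlation. The lower lists include the MiT-TFE family, which holds the targeted gene Tfeb itself.

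Across the 47 lists, 7 of the 44 that could be tested were called with the preset correlation, and none with an estimated correlation, where the smallest adjusted p was 0.794. The 7 include the MiT-TFE family list, which holds the targeted gene Tfeb itself. The fry test, which asks whether the genes of a list move on balance in one direction, called the macrophage and monocyte markers alone (adjusted p = 0.0477). Its mixed version, which counts changes in either direction, called 27 lists. Both versions test for change from 0 rather than relative to all genes. The median shift of 0.24 on the deposited scale therefore enters their calls. Adjusted over the list alone, higher members also numbered 2 for triacylglycerol and lipid droplet, 3 for sterol synthesis, 3 for fibroblast, 2 for smooth muscle and pericyte, 2 for macrophage and monocyte and 1 for circadian clock genes, and for the lists not given such a count here or elsewhere it equalled that over all genes tested. Of the 55 named genes past the threshold, 48 were lost in at least 1 alternative. Akr1b8, Pde7a, Ankrd1, Cox19, Ctsz and Pdk3 passed in all 19, and Psat1 in the 17 in which it was tested, since a filter of 5 CPM removed 14 of the 55 genes from the other 2. The number that passed in each scaling alternative in which they were tested was 40, of which 29 were tested in all. Among the rest, Art4, Ugp2, Nsdhl, Phlda3, Slc7a5 and Cspg4 were lost with quantile normalization (adjusted p = 0.055 to 0.0887). Tfeb aside, the number of these genes no longer called when 1 library was left out was 21, 28 and 29 for wild type 1, 2 and 3 and 25, 13 and 33 for TFEB-/- 1, 2 and 3, and none changed sign.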

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

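Rounding noise, median-ratio scaling with a filter of 5 CPM or with a GC correction, and CPM without mitochondrial transcripts were tried only after the data were seen, and count-based models were not run because whole reads could not be recovered. The 7 called lists were 5 to 9 in number under the settings that kept the preset camera test and 0 with an estimated correlation. Fry, which tests for change from 0, called 1 list, which was not among the 7. Of the 55 named genes past the threshold 0 changed sign in any alternative, 10 were no longer called with rounding noise and 12 passed in every alternative but the block in which they were tested, 8 of them in all, since a filter of 5 CPM removed Tgfa, Cda, Bok and Psat1. The pseudocounts and the absence of a filter left the counts of higher genes at 418 to 507 and of lower genes at 59 to 68. Correlations of the deviations from the group mean between libraries of the same number were 0.144, −0.0492 and 0.0883, so the numbers show no pairing, and the block uses up degrees of freedom. Rounding to whole CPM limits genes of a few CPM, and the depth of the libraries is unknown.

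The number of higher genes, 487, became 159 with the block, 780 with robust hyperparameters, 2241 with array weights, 813 with rounding noise and 244 with an absolute log2 fold change of at least 1, which only adds a limit. It ran from 248 without wild type 3 to 516 without TFEB-/- 2 when 1 library was left out, and was 270 without wild type 2 and 272 without TFEB-/- 3. The number of lower genes, 65, became 200 with median-ratio scaling, 172 with quantile normalization, 26 with the block, 338 with array weights, 220 with median-ratio scaling and a filter of 5 CPM, 244 with median-ratio scaling and GC correction, 169 without mitochondrial transcripts and 39 with the limit on the fold change. The array weights ran from 0.422 for wild type 3 to 3.66 for TFEB-/- 3, so that fit rests mainly on wild type 2 and TFEB-/- 3. Apart from the added limit, the cause was not tested. Tfeb kept its log2 fold change of −1.85 with the block while its adjusted p rose to 0.112, and it ran from −2.05 to −1.65 when 1 library was left out. List members that were higher, 33, became 56 with a filter of 5 CPM, 9 with the block, 66 with robust hyperparameters, 140 with array weights, 74 with rounding noise, 20 with the limit on the fold change and 17 to 29 when 1 library was left out. List members that were lower, 6, became 10 with a filter of 5 CPM, 24 with median-ratio scaling, 20 with quantile normalization, 3 with the block, 11 with robust hyperparameters, 38 with array weights, 29 with median-ratio scaling and a filter of 5 CPM, 34 with median-ratio scaling and GC correction, 23 without mitochondrial transcripts, 12 with rounding noise and 2 to 7 when 1 library was left out.

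The test of the interferon-stimulated genes turned to the other direction with a filter of 5 CPM (median −0.10 relative to all genes, adjusted p = 0.874) and with that filter and median-ratio scaling (median −0.10, adjusted p = 0.982), within a range of 0.000107 to 0.982. That filter left 9 of its 29 members.

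The other reversals were of log2 fold changes of genes not past the threshold. Rescaling removes the median shift of 0.24, so genes just above 0 turned negative. With median-ratio scaling, and alike with the added filter of 5 CPM, these were Atp6v0c −0.027, Tsc2 −0.097, Lamtor1 −0.052, Esrra −0.061, Calr −0.14, Atp5a1 −0.18, Egr1 −0.028, Hsp90ab1 −0.021, Bhlhe40 −0.12, Ddx3y −0.17 and Upk3b −0.19. Without mitochondrial transcripts the values were Atp6v0c −0.025, Tsc2 −0.095, Lamtor1 −0.050, Esrra −0.059, Calr −0.13, Atp5a1 −0.18, Egr1 −0.026, Hsp90ab1 −0.020, Bhlhe40 −0.12, Ddx3y −0.17 and Upk3b −0.19. With quantile normalization they were Atp6v0c −0.039, Tsc2 −0.12, Lamtor1 −0.073, Esrra −0.059, Calr −0.11, Atp5a1 −0.099, Nfkbia −0.0042, Bhlhe40 −0.12, Ddx3y −0.17 and Upk3b −0.22. With median-ratio scaling and GC correction they were Atp6v0c −0.14, Pink1 −0.12, Tsc2 −0.18, Lamtor1 −0.14, Esrra −0.21, Calr −0.13, Myh6 −0.032, Atp5a1 −0.23, Nfkbia −0.042, Egr1 −0.12, Hsp90ab1 −0.053, Bhlhe40 −0.14, Rplp0 −0.090 and Upk3b −0.25. With array weights, where the cause was not tested, Lamtor1 was −0.0088, Upk3b −0.12, Aqp1 0.28, Hba-a1 0.67 and Hbb-bs 0.57. When 1 library was left out, the range was −0.071 to 0.27 for Calr, −0.079 to 0.13 for Atp5a1, −0.094 to 0.31 for Bhlhe40, −0.43 to 0.22 for Hspa5 and −0.45 to 0.16 for Dbh, each lowest without wild type 3 and highest without wild type 1. It was −0.058 to 0.22 for Ddx3y, −1.38 to 0.39 for Hba-a1 and −1.04 to 0.12 for Hbb-bs, lowest without wild type 2 and highest without wild type 1. It was −0.19 to 0.20 for Upk3b (without TFEB-/- 2 and TFEB-/- 3) and −0.28 to 0.042 for Fabp4 (without TFEB-/- 3 and TFEB-/- 1).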

Other observations

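Most proliferation genes lay higher in TFEB-/- libraries relative to all genes, though camera did not call the list on the deposited scale. Values were highest in TFEB-/- 1 for several of them. Of 17 measured members 16 lay above the median of all genes (list median 0.81 above it), 0 passed the threshold in limma, 5 had an unadjusted p below 0.05 and 2 were higher when adjusted over the list alone. The camera adjusted p was 0.107 with CPM as deposited, 0.961 with an estimated correlation and 0.000269 with median-ratio scaling. Most members were of low abundance, and a filter of 5 CPM left 4 of the 17. With that filter and median-ratio scaling the camera adjusted p was 0.0382. The replication helicase subunit Mcm2 was at 4, 3 and 4 CPM in wild type and at 30, 7 and 12 CPM in TFEB-/-, the cell cycle regulator E2f1 was listed at 0 in wild type and at 9, 1 and 1 CPM in TFEB-/-, and the most abundant members, Ccnd2 and Ccnd1, were at 36.7 ± 10.7 and 82 ± 47.8 CPM and at 20.3 ± 3.06 and 34 ± 2.65 CPM. Mcm2 and E2f1, and the genes of the next paragraph, were picked out after their values were seen.

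Some genes were higher in every TFEB-/- library than in any wild-type library without passing the threshold, with wide spread in wild type. The slow myosin Myh7 was at 1136, 173 and 204 CPM in wild type and at 2025, 2335 and 1635 CPM in TFEB-/- (log2 fold change 2.53, SE 0.80, adjusted p = 0.158). The atrial protein Mybphl was at 13, 36 and 4 CPM in wild type and at 73, 57 and 65 CPM in TFEB-/- (log2 fold change 2.32, adjusted p = 0.179). The plasma glutathione peroxidase Gpx3 was at 121, 218 and 72 CPM in wild type and at 538, 324 and 412 CPM in TFEB-/- (log2 fold change 1.74, adjusted p = 0.114). With median-ratio scaling Gpx3 passed (adjusted p = 0.0482) and Myh7 and Mybphl did not.

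The split of reads between mt-Co3 and its nuclear copy Gm28437 differed widely between libraries. The copy held 32.2%, 14.6% and 2.57% of the pair in wild type and 53.8%, 58.8% and 36.2% in TFEB-/-, with no overlap between groups. Since their reads cannot be told apart, the split is not a measure of expression, and only the sum is interpretable (exact permutation p = 0.2).

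The tests on the mitochondrial share below and the settings with rounding noise, GC correction or a filter added to median-ratio scaling were chosen after the results were seen.

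Of the 10 ways to split the 6 libraries into 3 and 3, 1 called as many genes as the real split, the real one itself. The real split called 552 genes and the highest of the others 58, and 10 splits are too few for a share below 0.05.

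More genes were higher than lower in TFEB-/-, 487 against 65, or 88.2% of the 552 called. Scaling of CPM against a different mitochondrial share was tested by median-ratio scaling, after which 481 were higher and 200 lower, or 70.6% of 681, above a bound of 60% that was set after the excess was seen and before this test was run. Fold changes so scaled tracked GC content across 12410 genes, which are not independent replicates (Spearman 0.304, with a median GC of 55.0% in higher, 48.0% in lower and 51.1% in all tested genes), but with a GC correction added 67.1% of 742 called genes were still higher, so the tables argue, by a small margin, against either as the whole cause. With a filter of 5 CPM and median-ratio scaling the share was 62.6% of 588, and with rounding noise and median-ratio scaling 65.4% (400 higher and 212 lower), close to that bound, so the number of lower calls and the share depend on the scaling, and GC content may account for part of the excess. A difference between the genotypes and any unrecorded batch stay open, untested.

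A pattern of the calls themselves was that 164 of the 552 genes had no spread within either group. With uniform noise of up to 0.5 CPM on either side, 20 of these, 12.2%, were still called in the median draw, below a bound of 50% that was set after these calls were seen and before the noise was added. Rounding of the deposited values is therefore a candidate explanation for most of these calls, and no biological explanation was tested. Psat1 and Pdk3 were among the named genes with no spread that were still called.

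The mitochondrially encoded share was lower in TFEB-/-, by −10.5 percentage points. Reads divided with nuclear copies were tested by adding 5 such copies, which left 97.8% of the difference and argues against them as its source, although the sum no longer separated the groups (41.5 ± 7.41% and 31.2 ± 5.86%, exact permutation p = 0.2). If a lower share of cardiomyocytes raised the markers of all other cell types alike, endothelial and macrophage markers would both rise. However, 15 endothelial markers moved down (median −0.39 relative to all genes, quartiles −0.44 and −0.30). The 13 macrophage and monocyte markers, none above 20 CPM, moved up (0.37, quartiles 0.21 and 0.67). These quartiles also stayed apart with array weights (endothelial median −0.084, macrophage 0.43). The 14 fibroblast markers lay at 0.058 as deposited and at 0.12 with array weights, and the 12 smooth muscle and pericyte markers at −0.33 and −0.15. These values run against a rise of all other cell types alike, but weakly. The quartiles are over genes measured in the same 3 libraries per group, which are not independent replicates. Camera with an estimated correlation called neither list (adjusted p = 0.794 for endothelial and 0.961 for macrophage markers). A filter of 5 CPM left 2 of the 13 macrophage markers, and more macrophages stay open. Other cell types can vary separately, so the test cannot decide whether the share of cardiomyocytes differed. Ventricular cardiomyocyte markers had a median of −0.01 relative to all genes (camera adjusted p = 0.509). RNA quality, the isolation of the cells and the genotype itself may each be the source and were not tested.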
